A study of Homo sapiens with 6 samples.

How the data were processed

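Messenger RNA was measured in 6 libraries of HepG2 cells, 3 treated with DMSO and 3 with MI-503 for 6 days. Per the labels' protocols, RNA was isolated with a column kit, amplified, and made into libraries with a TruSeq mRNA kit. The submitters' processing notes name FastQC, Bowtie, TopHat, TopHat2 2.0.3, Cufflinks and the genome build hg19, with no role or order. The annotation, the strand setting and any filter are not given in the sources used here.

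The deposited table holds RPKM values, reads per kilobase of transcript scaled to the mapped reads, 1 value per gene symbol and library, as the authors made them. It has 25268 rows, of which 5304 are never above 0 and 2024 are small RNA genes, which a poly(A) library measures poorly. In 28 rows the symbol reads like a date, and 94 rows name several genes jointly. RPKM is no count, so no count test was run. Low RPKM values were searched for whole-read steps: over the pairs of DMSO replicates 2 and 3 and MI-503 replicates 2 and 3, the fullest bin of the ratios between libraries held 16.8 to 21.2 times as many genes as the bins around it, and over pairs with a replicate 1 library 1.4 to 1.7 times. The depths of those 4 libraries were estimated from the steps and transcript lengths of the GENCODE annotation of GRCh38, another build than the authors', so they are approximate. On simulated data made with the same transcript lengths the method returned 39900000 reads for 40000000, which does not test the lengths. No coordinates are given, because the builds differ. Transcript lengths were found for 12319 of the 13257 genes tested (92.9%).

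Genes with a mean of at least 0.5 RPKM over the 6 libraries were kept, 13257 in all. Values were taken as log2(RPKM + 1) without further scaling and compared with limma 3.58.1 (R 4.3.3) with a mean-variance trend, 2-sided, with groups as the only term. Benjamini-Hochberg adjustment ran over all genes kept, and a gene was called at an adjusted p under 0.05. Each gene's mean ± SD is over the 3 libraries of a group in RPKM, errors of log2 fold changes are limma's standard errors, and a fold such as 2.5-fold is the ratio of the group means in RPKM. On simulated data with the spread of the real comparison of MI-503 with DMSO over 13257 genes, limma called 17.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold, 95.5% of those changed 4-fold and 0.03% of unchanged genes. The simulated genes were independent, with equal spread in both groups and no trend on transcript length, so these shares need not hold for the real libraries. An exact 0 in this table can be a failed estimate, since genes used by every cell are listed at 0, so per-library values are given for such genes.

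Before the data were examined, 42 gene lists holding 1107 genes were fixed, 1091 of them found in the table, together with the test, the alternatives and the rule for named genes. The 39 lists with at least 5 tested members were compared with camera of limma at a preset correlation between genes of 0.01, repeated with an estimated correlation, under which none of the 10 calls held. The same lists were tested with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The text names 13 genes of prior interest whatever their values, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 2 RPKM and no overlap between groups, and up to 4 called members of each list called by camera or up to 3 of each other list. Near-identical relatives, such as ORM1 and ORM2 or members of the UGT2B, AKR1B and metallothionein families, can share reads in a way the sources used here do not describe.

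The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 2 RPKM, 3 other scalings, limma without the trend, with robust spread and with array weights, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were replicates 2 and 3 alone, a correction of each library for a smooth trend on transcript length, and leaving out small RNA genes or the pair FTL and TF. Figures and length tables used Python 3.11.15 with matplotlib 3.10.9.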

Results

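The series measured messenger RNA by sequencing in HepG2, a human liver cancer cell line, after treatment with MI-503, a small molecule that blocks the binding of menin to the histone methyltransferase MLL, or with its solvent dimethyl sulfoxide (DMSO). There were 3 DMSO and 3 MI-503 libraries, numbered as replicates 1 to 3 in each group, all harvested at day 6 with the compound given again at day 3. The labels disagree on the dose: the sample label gives 2 µM MI-503 and the protocol gives 3 µM, against 0.25% DMSO. The labels speak of triplicates without saying that the cultures were independent, so p-values measure only the spread between these libraries, which may be technical. The deposited table holds RPKM values for 25268 gene rows and no read counts. Depth could be estimated from whole-read steps among low values in 4 libraries, at about 44000000 reads in DMSO replicate 2, 43100000 in DMSO replicate 3, 46200000 in MI-503 replicate 2 and 51300000 in MI-503 replicate 3. The steps alone put DMSO replicate 3 at 1.02 times the depth of DMSO replicate 2, so the estimates do not rank these DMSO libraries. The replicate 1 library of either group did not share these steps, so its depth is unknown. All gene symbols are those of the table, and fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes.

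The comparison of MI-503 with DMSO asked which transcripts differ after treatment with the compound. With no other compound or knockdown in the series, effects of blocking menin-MLL cannot be told apart from other effects of MI-503. AFP, the fetal serum protein used as a liver cancer marker, fell 3.79-fold, from 2929 ± 248 to 774 ± 92.9 RPKM (SD, n = 3 per group), and PEG10, an imprinted retrotransposon-derived gene, fell 3.08-fold, from 489 ± 15.5 to 159 ± 39.3 RPKM, a fall that did not pass without DMSO replicate 1, 2 or 3 (limma adjusted p = 0.0535, 0.0569 and 0.0594; 4.74e-05 to 0.0595 over all alternatives). Of 39 lysosome and autophagy genes 22 rose, SQSTM1 (53.3 ± 2.03 to 180.4 ± 27.9 RPKM) among them, and the cytokine GDF15 rose from 53.8 ± 2.76 to 246 ± 84.4 RPKM. CYP1A1, a cytochrome P450 that oxidises aromatic compounds, rose 19.1-fold from a low level, 1.48 ± 0.197 to 28.3 ± 1.44 RPKM.

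Of 13257 genes tested with limma, 1064 were higher and 742 lower in MI-503 at an adjusted p under 0.05, and of these 229 were at least 2-fold higher and 82 at least 2-fold lower. The median log2 fold change of all tested genes was 0.01. The values of the groups did not overlap in 6335 genes, 47.8%, where chance gives 10%. MI-503 replicate 1 stood apart from MI-503 replicates 2 and 3, with short transcripts higher and long transcripts lower: its median log2 difference from them was 0.56 over genes of 300 to 1000 nucleotides and −0.54 at 8000 nucleotides or more. Without that library, 2518 genes were higher and 2101 lower, including 1064 and 741 of the genes called with all 6 libraries. In replicates 2 and 3 of both groups alone, 2840 were higher and 2498 lower, including 1051 and 726 of them, and no called gene changed sign in either subset. Leaving out another library gave 234 higher and 130 lower genes without DMSO replicate 1, 153 and 81 without DMSO replicate 2, 170 and 83 without DMSO replicate 3, 348 and 191 without MI-503 replicate 2, and 534 and 299 without MI-503 replicate 3. Rescaling every library to a sum of 1000000 took the median of all genes from 0.01 to −0.33 and gave 380 higher and 3575 lower genes, 9.6% higher in place of 58.9%. Of the 1806 genes called without rescaling, 1100 were called in the same direction after it and 133 changed sign. In the deposited table a single microRNA row, MIR6723, carried 601544 to 1769360 RPKM per library.

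Many genes passed by a narrow margin. Of 108 called genes chosen for naming, 43 passed limma on leaving out any 1 library, among them AFP, CYP1A1, GDF15, SQSTM1, NEU1, CTSA, CD68, NUPR1, AKR1B10, ABCC3, FGA, FGB, PROM1, ADH6, UGT2B10, BAAT, HPD, ASS1, GCKR, ENO2, PFKP, ACSS2, AGPAT2, AJUBA, NT5E, DKK1, OAS1, TNFAIP2, C19orf80, C8G, B3GNT3, LGALS3, S100A11, UBD, ODAM and 7 genes listed at 0 in a group. The other 65 kept their sign but did not pass without at least 1 library: 61 without DMSO replicate 1 (adjusted p up to 0.151), 63 without DMSO replicate 2 (up to 0.173), 63 without DMSO replicate 3 (up to 0.197), 45 without MI-503 replicate 2 (up to 0.123), 34 without MI-503 replicate 3 (up to 0.109) and SNORD67 without MI-503 replicate 1 (0.0616). With the replicate number as a block, which the labels do not ask for, AFP (adjusted p = 0.0541, the highest of its alternatives, from 5.04e-05), PEG10 (0.0595) and GDF15 (0.0511, from 5.06e-05) did not pass. Of all 1806 called genes, 193 passed with that block. Others of the 43 also failed an alternative, among them FGA (limma adjusted p up to 0.0576), FGB (0.0618), NUPR1 (0.0652) and HPD (0.0657).

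**Figure D1:**
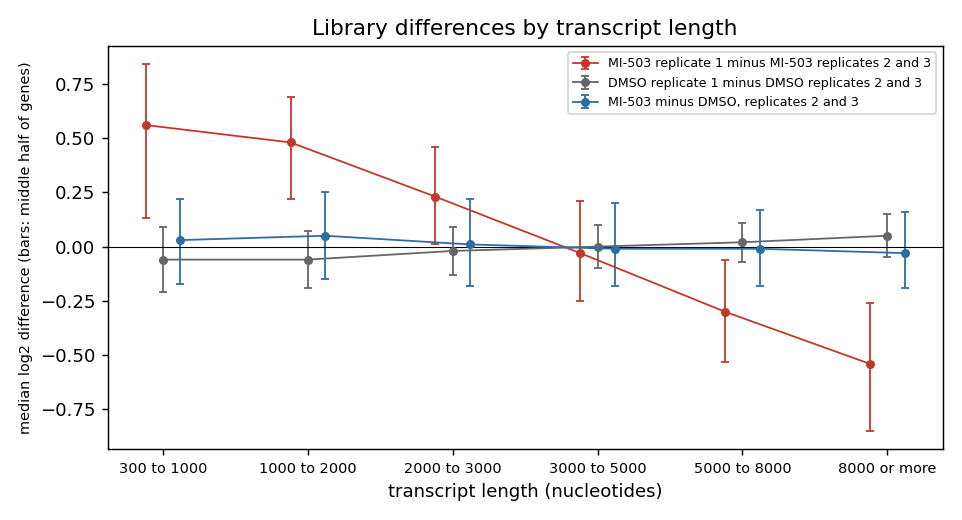
Median log2 difference between libraries in 6 bins of transcript length (nucleotides, horizontal axis), with bars for the interquartile range of the genes in each bin. MI-503 replicate 1 against the other MI-503 libraries runs from 0.56 in the shortest bin to −0.54 in the longest, while DMSO replicate 1 against the other DMSO libraries stays between −0.06 and 0.05.

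None of the 20 genes listed as menin-MLL complex subunits and partners passed limma with all 6 libraries. Of these, 3 had an unadjusted p under 0.05. MEN1, which encodes menin, was at 17.2 ± 0.291 RPKM in DMSO and 15.9 ± 1.87 in MI-503 (log2 fold change −0.12 ± 0.10 SE, limma adjusted p = 0.441). KMT2A, which encodes MLL, was at 6.20 ± 0.285 and 3.92 ± 1.98 RPKM (−0.65 ± 0.34, adjusted p = 0.230), with 1.64 RPKM in MI-503 replicate 1 against 4.90 and 5.22 in the others, and without that library its log2 fold change was −0.25 (adjusted p = 0.0303, and 0.0303 to 0.419 over its alternatives). Without MI-503 replicate 1, MEN1 (−0.21, adjusted p = 0.0194, and 0.00524 to 0.688 over its alternatives) and KDM6A (adjusted p = 0.0255) also fell and NCOA6 rose (adjusted p = 0.0457). PSIP1, a chromatin-binding partner of the complex, was at 33.9 ± 6.65 and 19.5 ± 3.33 RPKM (−0.76 ± 0.19, adjusted p = 0.0535, and 0.0522 without MI-503 replicate 1). In replicates 2 and 3 alone 4 fell, PSIP1 (−0.79, adjusted p = 0.00651), MEN1 (0.0230), KDM6A (0.0309) and PAXIP1 (0.03315), and JUND rose (0.0165). KMT2B was at 5.61 ± 0.552 and 5.67 ± 1.07 RPKM. The list gave camera adjusted p = 0.410, and 0 members passed when adjusted over the list alone.

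Imprinted genes moved in both directions: of 22 tested, 3 rose, 3 fell and 16 did not pass, with 4 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.108). PEG10 fell (log2 fold change −1.65 ± 0.20 SE, limma adjusted p = 0.00920) with all 6 libraries, as did SGCE, the gene that shares its promoter region (1.51-fold, −0.57 ± 0.09, adjusted p = 0.0172, and up to 0.0991 on leaving out 1 library). PHLDA2, a growth-restraining gene of the placenta, rose 7.23-fold from 0.563 to 4.07 RPKM, and SLC22A18 rose 2.13-fold. IGF2, a fetal growth factor, was at 398 ± 54.4 and 299 ± 90.8 RPKM and did not pass (adjusted p = 0.239). Among 8 tested genes listed as targets of MLL fusion proteins in leukaemia, 1 rose, 1 fell and 6 did not pass (camera adjusted p = 0.266). Adjusted over the list alone, 1 was higher and 3 were lower. PBX3 fell from 4.94 to 2.92 RPKM and CDK9 rose from 9.81 to 13.3 RPKM, a log2 rise that turned to −0.036 when libraries were rescaled to the same sum. MEIS1 was at 1.32 ± 0.188 and 0.870 ± 0.0992 RPKM (adjusted p = 0.0807). HOXA9 was at 0.00735 and 0.00372 RPKM, below the filter on low values. None of the 5 HOX genes tested passed limma, over the list alone, over all genes or at an unadjusted p under 0.05, with all 6 libraries (camera adjusted p = 0.999). Of them, 1 fell in replicates 2 and 3 alone. Among 7 CDK inhibitors, CDKN1A, which encodes p21, rose from 25.4 ± 1.08 to 39.6 ± 5.34 RPKM (0.61 ± 0.11, adjusted p = 0.0264, and 0.0898, 0.110, 0.127 and 0.0771 without DMSO replicates 1, 2 and 3 and MI-503 replicate 2) and 6 did not pass. CDKN1B was at 33.1 ± 1.47 and 26.6 ± 3.62 RPKM (adjusted p = 0.122) and CDKN2C at 10.7 ± 0.611 and 7.85 ± 2.19 RPKM (0.155). Without MI-503 replicate 1 both fell (0.00691 and 0.00427), as they did in replicates 2 and 3 alone (−0.38 and −0.67, adjusted p = 0.00844 and 0.00651), where CDKN2D rose (0.0452) and CDKN1A rose (0.0141). The list alone gave 1 higher, and camera adjusted p = 0.632.

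Markers of fetal liver and liver progenitors were lower as a list: of 21 tested, 3 fell, 0 rose and 18 did not pass, and 5 fell when adjusted over the list alone. For this list, camera gave adjusted p = 0.0475, and adjusted p = 0.670 with an estimated correlation. AFP fell (log2 fold change −1.92 ± 0.16 SE, limma adjusted p = 0.00355), with PEG10 and PROM1, a progenitor surface protein (5.24 ± 0.203 to 2.17 ± 0.0604 RPKM). GPC3, an oncofetal proteoglycan, was at 2538 ± 86.6 and 2063 ± 153 RPKM (−0.30 ± 0.15, adjusted p = 0.217, and −0.36 with adjusted p = 0.01997 without MI-503 replicate 1, 0.00267 to 0.483 over its alternatives). The call of this list was kept in 10 of 21 other camera settings at the preset correlation, with adjusted p from 0.0169 to 0.121. It was lost without DMSO replicate 1 (0.0792), DMSO replicate 2 (0.0651), MI-503 replicate 2 (0.121) or MI-503 replicate 3 (0.0541), in replicates 2 and 3 alone (0.0660), with the replicate number as a block (0.0781), with all 3 other scalings, with no filter and without small RNA genes.

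Genes of mature hepatocyte function went both ways. Of 43 secreted plasma proteins, 6 fell, 0 rose, 36 did not pass and TF was listed at 0 in DMSO, with 3 higher and 12 lower when adjusted over the list alone (camera adjusted p = 0.215, and 0.00280 to 0.678 over the other settings at the preset correlation). TF took part in the camera test of this list, which gave adjusted p = 0.0923 with TF and FTL left out. In replicates 2 and 3 alone 5 rose and 18 fell (camera adjusted p = 0.0168), and without MI-503 replicate 1 alone 6 rose and 19 fell, past the threshold for the list. The fibrinogen chains FGA (1776 ± 192 to 634 ± 47.9 RPKM) and FGB (285 ± 9.05 to 149.8 ± 7.99 RPKM) fell. Of 12 acute phase proteins, 3 rose (SAA4 4.18-fold, ORM1 2.41-fold and ORM2 2.13-fold), 2 fell and 7 did not pass, with 5 higher and 5 lower over the list alone (camera adjusted p = 0.959). ORM1 and ORM2 are near-identical, so their values are uncertain. Among 25 cytochrome P450 and drug metabolism genes, 5 rose, 6 fell and 14 did not pass, with 8 higher and 6 lower over the list alone (camera adjusted p = 0.619). In that list, CYP1A1 rose (3.56 ± 0.09, adjusted p = 1.05e-04), and UGT2B10, a glucuronosyltransferase, and the alcohol dehydrogenase ADH6 fell 3.65-fold and 2.89-fold.

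For 28 liver-enriched transcription factors, 2 rose, 2 fell and 24 did not pass, with 2 and 2 over the list alone (camera adjusted p = 0.937). NR0B2, a nuclear receptor that represses bile acid synthesis, rose from 34.0 to 83.5 RPKM, while CREB3L3 and HNF4G fell 1.99-fold and 1.66-fold. Of 16 bile acid genes, 2 rose, 3 fell and 11 did not pass, with 3 and 3 over the list alone (camera adjusted p = 0.952). The bile acid exporter subunit SLC51B rose 2.89-fold and BAAT, which conjugates bile acids, fell 6.31-fold. Urea cycle and amino acid breakdown had 6 higher, 4 lower and 20 not passed of 30, with 8 and 7 over the list alone (camera adjusted p = 0.957). There HPD, of tyrosine breakdown, rose 2.85-fold, and the urea cycle genes ASS1 and NAGS rose 2.91-fold and 4.74-fold. Of 14 gluconeogenesis and glycogen genes, 2 rose (GCKR 2.32-fold, PC 1.53-fold), 1 fell (the glucose transporter SLC2A2, 2.52-fold) and 11 did not pass, with 3 and 1 over the list alone (camera adjusted p = 0.515).

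Lysosome and autophagy genes of the network controlled by the transcription factor TFEB were higher in MI-503. Of 39 tested, 22 rose, 0 fell and 17 did not pass, with a median log2 fold change of 0.62, and 30 rose when adjusted over the list alone. Tested as a list, they gave camera adjusted p = 5.35e-11, and adjusted p = 0.670 with an estimated correlation. In replicates 2 and 3 alone, 31 rose and 0 fell (camera adjusted p = 8.18e-11, and 1.87e-15 to 1.59e-09 over the other settings at the preset correlation). With libraries rescaled to the same sum 11 rose and 1 fell, and the list's median was 0.17, above that of all genes by 0.50. SQSTM1, an autophagy receptor, had a log2 fold change of 1.73 ± 0.13 (SE, limma adjusted p = 0.00301). The sialidase NEU1 rose from 83.8 ± 2.90 to 238 ± 49.2 RPKM, and the cathepsins CTSA and CTSD rose 2.71-fold and 2.57-fold.

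Target genes of ATF4, the transcription factor of the amino acid and unfolded protein stress response, were also higher. Of 30 tested, 14 rose, 0 fell and 16 did not pass, and 18 rose when adjusted over the list alone. The list gave camera adjusted p = 6.69e-07, and adjusted p = 0.670 with an estimated correlation. With libraries rescaled to the same sum 4 rose and 3 fell (camera adjusted p = 4.74e-05, the highest of the other settings at the preset correlation, from 3.46e-09). GDF15, a stress cytokine, rose 4.58-fold (2.12 ± 0.24 SE, limma adjusted p = 0.00676), NUPR1 rose 3.94-fold, the pseudokinase TRIB3 2.42-fold and DDIT3, which encodes CHOP, 2.16-fold. Of 24 endoplasmic reticulum chaperones, 0 rose with all 6 libraries, 1 fell (PDIA4, 192 to 143.9 RPKM) and 23 did not pass, with 0 over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.632).

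Among 26 target genes of the oxidative stress factor NRF2, 7 rose, 0 fell, 18 did not pass and FTL was listed at 0 in MI-503, with 8 higher over the list alone. For this list, camera gave adjusted p = 0.0269, and adjusted p = 0.804 with an estimated correlation, and of the other camera settings at the preset correlation (0.00253 to 0.0671) it was lost without MI-503 replicate 2 (0.0671). FTL took part in the camera test, which gave adjusted p = 0.00253 with FTL and TF left out. AKR1B10, an aldo-keto reductase, rose 5.53-fold and the exporter ABCC3 2.75-fold. Of 9 metallothioneins and zinc genes, MT2A rose 3.55-fold and 8 did not pass, with 3 higher and 1 lower over the list alone (camera adjusted p = 0.515). Of 17 heat shock genes, 1 fell (CHORDC1, 14.6 to 10.4 RPKM), 0 rose and 16 did not pass, with 0 over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.266). The p53 targets had 5 higher, 6 lower and 22 not passed of 33, with 5 and 8 over the list alone (camera adjusted p = 0.381), including falls of EDA2R and the DNA repair gene DDB2 (24.3 ± 1.65 to 13.3 ± 0.730 RPKM). Of 13 BCL2 family genes, BAK1, BID and BCL2L2 rose (1.58-fold, 1.45-fold and 1.30-fold), 0 fell and 10 did not pass, with 5 higher and 1 lower over the list alone (camera adjusted p = 0.510). BCL2L2 turned to −0.10 on the log2 scale when libraries were rescaled to the same sum. Over the alternatives the log2 fold changes of BID and BAK1 went down to 0.040 and 0.14, with limma adjusted p up to 0.777 and 0.237. Hypoxia genes had 2 higher, 4 lower and 17 not passed of 23, and 2 and 4 over the list alone (camera adjusted p = 0.108, at 0.0228 without MI-503 replicate 3, and 0.00818 with array weights to 0.560 over all other settings at the preset correlation, 2 of 21 called), with P4HA1 falling 1.95-fold and the glucose transporter SLC2A1 rising 1.62-fold.

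**Figure D2:**
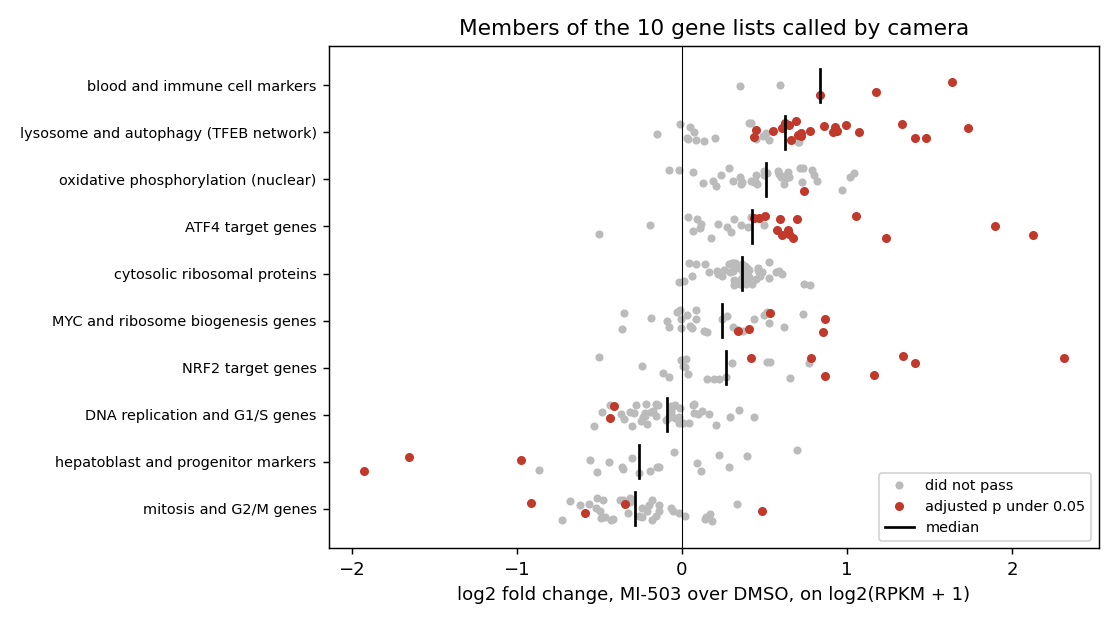
Log2 fold change, MI-503 over DMSO on log2(RPKM + 1), of each tested member of the 10 gene lists called by camera (horizontal axis), with genes that passed limma at an adjusted p under 0.05 in red, the rest in grey, and a bar at each list's median. FTL, listed at 0 in MI-503, is left out. In the lysosome list 22 of 39 members passed, all of them higher.

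Cell cycle genes were lower as lists, with few members passing with all 6 libraries. Rescaling libraries to the same sum gave 17 mitosis and 22 DNA replication genes lower and 0 higher, but over all genes 3575 lower and 380 higher. Less the median of all genes, the medians of these 2 lists were −0.35 and −0.19 after rescaling, against −0.29 and −0.1 without it. Of 40 mitosis and G2/M genes, 3 fell (the kinesin KIF20A 1.98-fold, NUSAP1 1.53-fold and CDK1 1.28-fold), 1 rose (the phosphatase CDC25B, 1.43-fold) and 36 did not pass, with 0 over the list alone and 12 at an unadjusted p under 0.05. Tested as a list, they gave camera adjusted p = 0.00308, and adjusted p = 0.819 with an estimated correlation. In replicates 2 and 3 alone, 28 members fell and 2 rose (camera adjusted p = 1.42e-07, against up to 0.0231 in other settings at the preset correlation). Of 46 DNA replication genes, 2 fell (GINS1 1.37-fold among them), 0 rose and 44 did not pass, with 1 lower over the list alone (camera adjusted p = 0.0475, adjusted p = 0.819 with an estimated correlation). Over the other camera settings at the preset correlation (7.23e-05 to 0.207) that call was lost with no filter (0.0866), with libraries shifted to the same median (0.0618), without small RNA genes (0.0531) and without DMSO replicate 2 (0.179), DMSO replicate 3 (0.156), MI-503 replicate 2 (0.0671) or MI-503 replicate 3 (0.207), whereas in replicates 2 and 3 alone 20 fell and 3 rose (7.23e-05). MYC was at 81.3 ± 2.05 and 76.7 ± 10.8 RPKM (limma adjusted p = 0.604, and −0.20 on the log2 scale with adjusted p = 0.0332 without MI-503 replicate 1, 0.0134 to 0.922 over its alternatives). Of 33 MYC and ribosome biogenesis genes, 5 rose, 0 fell and 28 did not pass, with 8 higher over the list alone. The list gave camera adjusted p = 0.0269, and adjusted p = 0.819 with an estimated correlation, and over the other camera settings at the preset correlation (0.00469 to 0.207) was lost without DMSO replicate 1 (0.138) or MI-503 replicate 2 (0.114), in replicates 2 and 3 alone (0.110) and with libraries rescaled to the same sum (0.207). RRP9 and the spermidine synthase SRM rose 1.88-fold and 1.87-fold, and WDR12 and RRP12 rose 1.46-fold and 1.35-fold, with RRP12 at −0.041 on the log2 scale after rescaling to the same sum.

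Short and abundant transcripts of ribosomes and mitochondria were higher as lists, with 1 member passing in all. None of the 49 cytosolic ribosomal proteins passed limma, over the list alone or over all genes, and 1 had an unadjusted p under 0.05, although their median log2 fold change was 0.37 (camera adjusted p = 0.00502, adjusted p = 0.819 with an estimated correlation). Without MI-503 replicate 1, the library with higher short transcripts, the median was 0.09 and the call was lost (camera adjusted p = 0.282), as it was in replicates 2 and 3 alone (0.493), with array weights (0.508) and with libraries rescaled to the same sum (0.0794), the other settings at the preset correlation going down to 2.82e-04. The call was kept in 17 of 21 such settings, among them the correction for transcript length (median 0.174, camera adjusted p = 0.0414). Of 38 nuclear-encoded oxidative phosphorylation genes, SDHB rose 1.70-fold, 0 fell and 37 did not pass, with 0 over the list alone and 16 at an unadjusted p under 0.05 (camera adjusted p = 1.55e-05, adjusted p = 0.819 with an estimated correlation). Without MI-503 replicate 1, 23 of them rose and 0 fell (camera adjusted p = 1.44e-06, and 2.85e-07 to 7.60e-05 over the other settings at the preset correlation). Rescaling libraries to the same sum turned the medians of the ATF4, NRF2, MYC and ribosomal protein lists to −0.03, −0.24, −0.24 and −0.12, which stayed above the median of all genes by 0.31, 0.10, 0.09 and 0.21. The rescaled counts were 4 higher and 5 lower for NRF2 (FTL included), 1 and 2 for MYC, 0 and 4 for ribosomal proteins, 2 and 3 for oxidative phosphorylation, and 0 and 11 for fetal liver markers. Over all genes they were 380 and 3575.

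In carbohydrate and lipid metabolism no list passed with all 6 libraries before any alternative was applied. Of 22 glycolysis genes, 5 rose (ENO2 2.47-fold and PFKP 3.23-fold among them), 3 fell (the glucose transporter SLC2A3 2.03-fold among them) and 14 did not pass, with 5 and 3 over the list alone (camera adjusted p = 0.507). Of 26 cholesterol synthesis genes, 3 fell (SQLE 1.47-fold and CYP51A1 1.27-fold among them), 0 rose and 23 did not pass, with 3 lower over the list alone (camera adjusted p = 0.632). Of 22 fatty acid synthesis genes, 4 rose, 0 fell and 18 did not pass, with 4 higher over the list alone (camera adjusted p = 0.142, and 0.00260 to 0.368 over the other settings at the preset correlation, at 0.00630 without MI-503 replicate 1, with 9 higher and 1 lower). This list was called in 4 of the 21 other settings, among them the correction for transcript length with all 6 libraries (camera adjusted p = 0.0219). AGPAT2, which makes phosphatidic acid, rose 9.02-fold, ACSS2 1.81-fold and DGAT2, of triglyceride synthesis, 1.42-fold. Of 27 fatty acid oxidation genes, 2 rose, 3 fell and 22 did not pass, with 3 and 8 over the list alone (camera adjusted p = 0.268, and 0.0202 to 0.560 over the other settings at the preset correlation, at 0.0482 without MI-503 replicate 1). CPT1A, which admits fatty acids to mitochondria, rose 2.36-fold.

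Signalling targets were mixed, with no list called by camera in any setting, while fry called the YAP and TEAD list lower (adjusted p = 0.0274). Of 17 YAP and TEAD targets, 4 fell (AJUBA 2.07-fold and NT5E 2.12-fold among them), ANKRD1 rose 2.26-fold and 12 did not pass, with 2 higher and 6 lower over the list alone (camera adjusted p = 0.108). Of 19 WNT targets, 3 rose, 3 fell and 13 did not pass, with 3 and 5 over the list alone (camera adjusted p = 0.451). The WNT inhibitor DKK1 fell 2.44-fold, the stem cell receptor LGR5 fell 1.80-fold and DKK4 rose 3.11-fold. Of 25 TGF-beta and matrix genes, 5 rose, 3 fell and 17 did not pass, with 6 and 3 over the list alone (camera adjusted p = 0.515), and TIMP1, TGFB1 and CDH1, which encodes E-cadherin, rose 2.80-fold, 2.15-fold and 2.15-fold. Of 28 interferon response genes, 3 rose (OAS1 2.61-fold and GBP2 2.02-fold among them), 2 fell (IFIT1 2.72-fold among them) and 23 did not pass, with 3 and 2 over the list alone (camera adjusted p = 0.451). Of 13 NF-kB and cytokine genes, 3 rose, 2 fell and 8 did not pass, with 5 and 3 over the list alone (camera adjusted p = 0.715). TNFAIP2 rose 10.5-fold from 0.248 RPKM, ICAM1 rose 1.67-fold and TNFAIP3 fell 1.72-fold.

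Markers of other cell types were mostly below the filter. Of the 26 blood and immune markers 5 were tested, of which CD68, a lysosomal membrane protein (3.30-fold), FCER1G (1.47 to 4.75) and CD14 (2.33 to 5.01) rose, 0 fell and 2 did not pass, with 5 higher over the list alone (camera adjusted p = 0.00308, adjusted p = 0.804 with an estimated correlation). That call was lost with no filter on low values (0.221). The leukocyte gene PTPRC was at 0.00176 RPKM in DMSO and 0 in MI-503. Of the 15 cholangiocyte and squamous markers 5 were tested, of which SPP1 (123 ± 10.5 to 254 ± 36.3 RPKM) and SFN (2.59 to 6.68) rose, 0 fell and 3 did not pass, with 2 higher over the list alone (camera adjusted p = 0.530). The fibroblast and endothelial lists had 3 and 2 genes above the filter, too few to test, and the table holds 0 of the 15 mitochondrially encoded genes. Of 14 replication-dependent histone genes, HIST2H2BE rose 1.56-fold and 13 did not pass, with 1 higher over the list alone (camera adjusted p = 0.515).

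Most lists that camera did not call gave other counts without MI-503 replicate 1. Given as higher and lower without it, then in replicates 2 and 3 alone, they were 3 and 8, then 5 and 11 for endoplasmic reticulum chaperones, 4 and 1, then 3 and 2 for heat shock genes, and 7 and 12, then 9 and 12 for p53 targets. Imprinted genes had 4 and 9, then 4 and 7. MLL fusion targets had 1 and 3 in both. For liver transcription factors they were 4 and 7 in both, for drug metabolism 11 and 6, then 11 and 7, and for bile acid genes 5 and 5, then 6 and 4. For amino acid breakdown they were 8 and 8, then 8 and 9. Gluconeogenesis had 5 and 3, then 5 and 4, glycolysis 7 and 5, then 9 and 5. Cholesterol synthesis had 2 and 6, then 5 and 6, and fatty acid oxidation 5 and 11, then 5 and 13. YAP targets had 2 and 7 in both, WNT targets 4 and 6, then 5 and 6. Matrix genes had 7 and 7, then 6 and 5, interferon genes 8 and 3, then 7 and 5, and NF-kB genes 5 and 4, then 4 and 4. Acute phase proteins had 3 and 5, then 4 and 5, metallothioneins 3 and 2, then 3 and 1, and BCL2 family genes 4 and 2 in both. Histone genes had 2 and 2, then 1 and 0, as against 1 and 0 with all 6 libraries. Hypoxia genes had 2 and 5 in both, cholangiocyte markers 2 and 0, then 2 and 2, and HOX genes 0 and 0, then 0 and 1.

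For 6 lists that camera did not call, the median, the mean and the test differed in sign: acute phase proteins (median −0.12, mean 0.16, camera lower), bile acid genes (median 0.08, camera lower), cholesterol synthesis (0.0040 and −0.016, camera lower), endoplasmic reticulum chaperones (0.05 and −0.02, camera lower), NF-kB genes (−0.02 and 0.16, camera higher) and cholangiocyte markers (−0.06 and 0.33, camera higher). With fry, 3 lists were higher, those of lysosome (adjusted p = 0.00297), ATF4 (0.00738) and blood and immune genes (0.0136), and 5 were lower, those of fetal liver markers (0.00216), MLL fusion targets (0.0136), NRF2 targets (0.0136), p53 targets (0.0190) and YAP targets (0.0274). The NRF2 list went the other way with fry than with camera, and it holds FTL, listed at 0 in MI-503. With an estimated correlation camera called 0 lists, and 2 had an unadjusted p under 0.05.

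The largest rises by the rule for named genes, besides CYP1A1 and AKR1B10, were C19orf80, which encodes the secreted lipoprotein lipase regulator ANGPTL8 (20.2 ± 3.28 to 162 ± 51.3 RPKM), the galectin LGALS3 (7.79-fold), the calcium-binding protein S100A11 (6.27-fold), AGPAT2, the complement chain C8G (7.72-fold) and the glycosyltransferase B3GNT3 (6.70-fold, limma adjusted p = 0.00237). The largest falls, besides AFP, included the extracellular matrix protein RELN (84.9 ± 4.59 to 20.9 ± 8.95 RPKM), the ubiquitin-like UBD (69.4 ± 15.7 to 15.8 ± 2.18 RPKM) and ODAM (40.2 ± 1.72 to 10.1 ± 1.66 RPKM). Several rows were listed at 0 in a whole group and carry no fold change. FTL, the ferritin light chain, was at 4364, 4948 and 4794 RPKM in DMSO replicates 1 to 3 and listed at 0 in all MI-503 libraries. TF, which encodes transferrin, was listed at 0 in all DMSO libraries and at 2653, 2168 and 2323 RPKM in MI-503 replicates 1 to 3. ALB, APOB, FN1 and EEF1A1, abundant in these cells or in every cell, were listed at 0 in all 6 libraries, so a 0 does not show absence. Of small RNA rows, MIR6514 was at 189, 87.1 and 85.4 RPKM in DMSO, MIR8086 at 26.4, 51.0 and 16.7, MIR6843 at 6.15, 8.53 and 10.5, and SNORA2B at 7.36, 6.26 and 3.07, each listed at 0 in all MI-503 libraries. SNORD67 was at 30.7, 45.3 and 15.0 RPKM in DMSO and at 0, 7.19 and 0 in MI-503, and SNORA80B at 0 in DMSO and 3.74, 3.08 and 5.59 in MI-503.

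**Figure D3:**
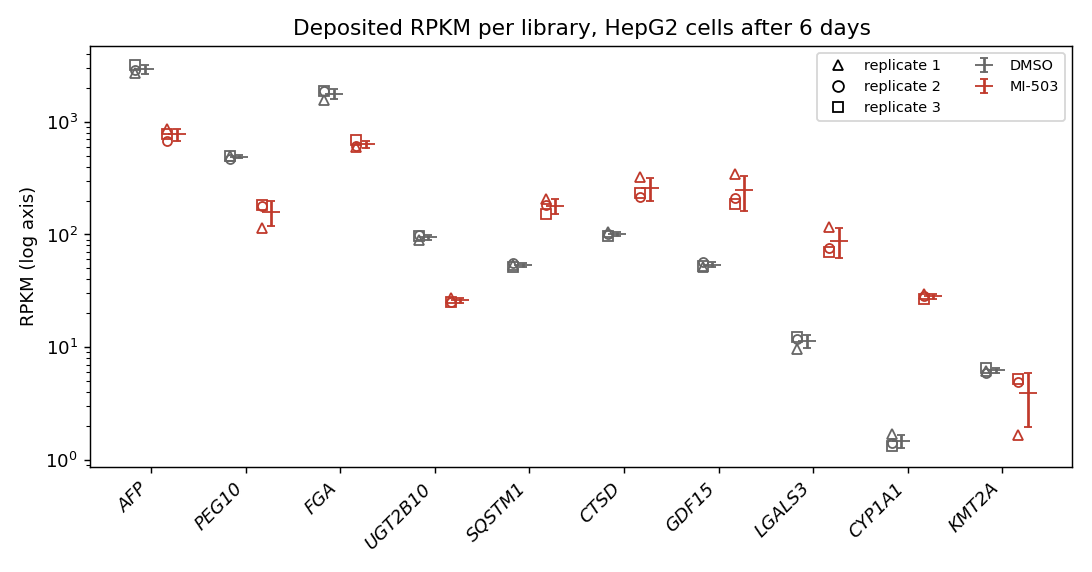
Deposited RPKM (log axis) of 10 genes in each library, DMSO in grey and MI-503 in red, with symbols for replicates 1 to 3 and bars for the mean and SD of 3 libraries. AFP falls from 2929 to 774 RPKM and CYP1A1 rises from 1.48 to 28.3 RPKM with no overlap between groups, and KMT2A lies at 1.64 RPKM in MI-503 replicate 1.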

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

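With all 6 libraries, limma called 1064 genes higher and 742 lower, 229 and 82 of them at least 2-fold, and camera called 7 lists higher and 3 lower. Leaving out 1 library gave 153 to 2518 genes higher and 81 to 2101 lower, 104 to 227 genes at least 2-fold higher and 1 to 5 lists lower. The most genes higher and lower came without MI-503 replicate 1 and the fewest without DMSO replicate 2. Array weights gave 3598 genes higher, 3231 lower and 6 lists lower, with a weight of 0.051 for MI-503 replicate 1. Rescaling to a sum of 1000000 gave 380 and 3575 genes, 53 and 296 at least 2-fold. A pseudocount of 0.1 gave 162 genes at least 2-fold lower, since low genes then have larger folds. No filter, a shift to the same median, and leaving out small RNA genes (chosen after seeing the data) each gave 1 list lower. Of other alternatives chosen after seeing the data, replicates 2 and 3 alone gave 2840 genes higher and 2498 lower, and a correction for transcript length gave 1611 and 1393. With an estimated correlation camera called 0 lists higher and 0 lower (2 at an unadjusted p under 0.05), and fry called 3 higher and 5 lower. For the rest the cause was not tested.

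The labels do not say that replicate numbers pair the libraries, and the values give no clear pairing: deviations from the group means correlated at 0.05, 0.01 and 0.19 for replicates 1, 2 and 3, and not every library correlated best with its own number (MI-503 replicate 1 with DMSO replicate 2, 0.093, and MI-503 replicate 2 with DMSO replicate 3, 0.11), a hint from the data only. With the replicate number as a block, 137 genes were higher and 56 lower, 101 and 47 at least 2-fold, with fewer degrees of freedom. Both replicate 1 libraries lack the read steps the other 4 share, so a separate batch for replicate 1 is not excluded.

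Of 108 called genes chosen for naming, 105 reversed under no alternative, and over 2254 pairs of such a gene and an alternative 1857 stayed called and 394 were no longer past the threshold. CDK9, RRP12 and BCL2L2 turned to −0.036, −0.041 and −0.10 on the log2 scale with libraries rescaled to 1000000, and KMT2B, at 0.0044 and not called, to −0.35 there, to −0.067 with upper-quartile scaling and to between −0.10 and 0.13 on leaving out 1 library. The rescaling divides each library by its summed RPKM, 1567113 to 1716607 in DMSO and 1981949 to 2834092 in MI-503. Without small RNA rows the sums were 470056 to 502289 in DMSO and 503537 to 728242 in MI-503. The turns under rescaling thus depend on a divisor made mostly of small RNA rows, which a poly(A) library measures poorly. The cause of the other changes was not tested. The NRF2 list turned lower with fry (adjusted p = 0.0136), a test in which FTL, listed at 0 in MI-503, takes part, as it does in camera. Over 47 pairs of a list and an alternative, involving 11 lists, the direction changed with the list called in neither fit (adjusted p = 0.288 to 0.996). It was decided after these values were seen not to count them as reversals, since no direction is claimed for such lists. Depth, known in 4 libraries and by estimate, limits low genes most.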

Other observations

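The genes in this paragraph lie outside the lists, were chosen after their values were seen and were not tested as groups, so they say nothing of actin or lysosomal genes at large. ACTB rose from 672 ± 22.8 to 1721 ± 444 RPKM (SD, n = 3; log2 fold change 1.33 ± 0.20 SE, limma adjusted p = 0.0155) and ACTG1 from 791 ± 27.9 to 2182 ± 475 RPKM, both often used as reference genes. Of other genes with roles in the actin cytoskeleton, ZYX, TAGLN2, MYL9 and TMSB4X rose 2.65-fold, 2.43-fold, 3.18-fold and 2.96-fold, while TMSB10 (adjusted p = 0.185), the actin-severing CFL1 (0.0735) and the tubulins TUBB (0.159) and TUBA1B (0.337) did not pass. CFL1 passed in replicates 2 and 3 alone (0.46, adjusted p = 0.0178), where TMSB10, TUBB and TUBA1B did not. All 6 that rose stayed higher in replicates 2 and 3 alone, with log2 fold changes from 1.02 to 1.25, and with libraries rescaled to the same sum, from 0.72 to 0.95. The lysosomal enzyme ASAH1, a ceramidase, rose from 46.6 ± 0.946 to 179 ± 6.92 RPKM, IFI30 from 25.7 ± 2.15 to 117 ± 30.4 RPKM and CTSH from 109 ± 10.6 to 273 ± 43.5 RPKM. S100P rose 4.39-fold, and S100A6 did not pass (adjusted p = 0.0583), except in replicates 2 and 3 alone (0.94, adjusted p = 0.00561). S100A4 (−0.33, adjusted p = 0.469) and S100A10 (−0.05, 0.928) did not pass either, and in replicates 2 and 3 alone S100A4 fell (−0.72, adjusted p = 0.0347) and S100A10 did not pass (−0.41, 0.0935). A search of 358 groups of genes by the first letters of their symbols, with Fisher's exact test in either direction, gave no group past the threshold (lowest adjusted p = 0.260, 37 of 716 tests at an unadjusted p under 0.05).

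Around PEG10 in the order of the annotation, SGCE fell, and the next genes CASD1 (log2 fold change −0.50 ± 0.14 SE, limma adjusted p = 0.0641), PPP1R9A (−0.49 ± 0.26, adjusted p = 0.233) and BET1 (−0.32 ± 0.10, adjusted p = 0.0937) did not pass, nor did PON3 (0.14), PON2 (0.14) and ASB4 (−0.14). In replicates 2 and 3 alone CASD1 was at −0.31 (adjusted p = 0.0144), BET1 at −0.36 (adjusted p = 0.0120) and PPP1R9A at −0.18 (adjusted p = 0.0655), against −1.41 for PEG10 and −0.67 for SGCE.

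Below, the tests of transcript length, of blood cell RNA and of cholesterol genes were chosen after the results were seen, and the tests of response size, of the aryl hydrocarbon receptor and of splits were written before. MI-503 replicate 1 stood apart from the other MI-503 libraries. A trend on transcript length took 38.0% of the variance of its difference from them over 11787 genes, against 2.5% for DMSO replicate 1, which is consistent with a technical difference such as RNA fragmentation, though its source is open. After the trend was removed, the difference between MI-503 and DMSO in replicate 1 had a slope of 1.13 (95% bootstrap interval 1.11 to 1.15 over 4975 genes, which are not independent) on that of replicates 2 and 3, over genes called in replicates 2 and 3. That slope rests on 1 library of each group, which only share a number, and an interval over genes cannot show that 1 culture responded more, so this stays open.

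The rise of lysosome genes was weighed against technical explanations. Length bias of MI-503 replicate 1 does not account for it, since the list's median log2 fold change was 0.578 in replicates 2 and 3 alone, against 0.623 with all 6 libraries. RNA from blood cells or macrophages accounts poorly for it: although CD68 rose by 24.4 RPKM, the summed rise of PTPRC, TYROBP, LAPTM5, SPI1, CSF1R and ITGAM was 1.60% of that. Other markers went with it: CD14 and FCER1G rose by 2.68 and 3.28 RPKM, and LYZ, at 1188 RPKM in DMSO and 1804 in MI-503, passed over the list alone though not over all genes, its difference of 616 RPKM being larger than that of CD68. But TYROBP was at 0.0174 RPKM and PTPRC at 0 in MI-503. A hypothesis that cholesterol held in lysosomes could raise SREBP2 targets was left undecided, with 5 members of the cholesterol list higher and 6 lower in replicates 2 and 3 (exact sign test p = 1). Its criterion was changed after the result was seen, by requiring that sign test, which moved the outcome from argued against to open. With so few members past the threshold, that sign test could count against the hypothesis only if nearly all of them fell. The cholesterol list showed no rise as a set. Its median log2 fold change was 0.001 in replicates 2 and 3, and 0.004 with all 6 libraries, where 0 members rose and 3 fell. A lysosomal response to the drug stays open as a hypothesis, and the camera call was lost with an estimated correlation.

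For CYP1A1, length bias of MI-503 replicate 1 does not account for the rise, since the log2 fold change was 3.60 in replicates 2 and 3 alone. Activation of the aryl hydrocarbon receptor is a candidate explanation: of 6 other targets, CYP1A2, CYP1B1 and AHRR were below the filter, and 1 of the 3 tested rose, NQO1 (216.5 ± 6.50 to 375 ± 49.7 RPKM), which is also an NRF2 target. TIPARP had a log2 fold change of 0.16 ± 0.17 (limma adjusted p = 0.527), and 0.32 in replicates 2 and 3 alone (adjusted p = 0.0386). ALDH3A1 was at 0.21 ± 0.13 (limma adjusted p = 0.311), and 0.046 in replicates 2 and 3 alone (adjusted p = 0.756). With so few targets expressed, these data leave it open.

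The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes higher, lower, at least 2-fold higher and at least 2-fold lower, the real split gave 1064, 742, 229 and 82 and the highest other split 7 in each case, so 1 of the 10 splits, the real one, gave as many. For lists, the real split gave 7 higher and 3 lower and the highest other split 8, counting the larger direction, so that 4 and 9 of the 10 splits gave as many.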
